A study of Mus musculus with 8 samples.

How the data were processed

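The samples were retinas of rd10 mice, a strain in which a mutation of Pde6b, the rod phosphodiesterase subunit gene, leads to loss of rod and then cone photoreceptors. The labels gave 4 libraries of a group named sIVs, small intracellular vesicles by the series title, and 4 of a group named PBS, read here as phosphate-buffered saline. Each library was assigned to its group and number by its title, so that the sIVs libraries are numbered 2 to 5 and the PBS libraries 1 to 4. The vesicle source, dose, route, age, sex and time of sampling were not given in the sources used here. The labels number the libraries as replicate biosamples but do not say whether each came from 1 animal, so p-values measure the spread between these libraries.

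Per the labels' protocols, RNA was extracted with TRIzol, messenger RNA was selected by its poly(A) tail, strand-marked libraries were made with dUTP, and paired-end reads were sequenced on an Illumina instrument. The submitters' processing notes name the mm10 genome build. The aligner, the counting program, the annotation release and the strand setting of the counting were not given in the sources used here. The deposited count table held whole-number, unnormalised counts for 54532 genes in 8 libraries. The deposited FPKM table held the same genes and libraries. Within each library every FPKM value equalled the count scaled to gene length and library total times 1 constant, within a tolerance of 0.1%, and that constant ran from 0.930 to 1.03. How the authors set the constant was not stated. It lay within 1% of the reciprocal of the TMM (trimmed mean of M values) factor computed here. Of the gene identifiers, 54409 were also in GENCODE M21, all on the same chromosome and 53499 with identical start and end, so coordinates from the deposited gene table are GRCm38.

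Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the group, which left 17725. Libraries were scaled by TMM, and glmQLFit and glmQLFTest were run with the group as the only term, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values are counts scaled to the TMM-adjusted library size. Standard errors of log2 fold changes were derived from the test's F statistic. Gene lists were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 42 lists with at least 5 tested genes. Each list was also tested with camera with an estimated correlation, with fry in its directional and mixed forms, and by counting members past 0.05 when adjusted over the list alone. Values of a library as a whole were compared by exact two-sided permutation tests over 70 relabellings, whose smallest possible p is 0.0286.

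The 46 gene lists covered photoreceptors, gliosis, microglia, complement, inflammation, cell death, survival factors, antioxidant genes and synapses as 12 primary lists, and 34 lists of cell type markers and cellular processes. Lists, tests and all alternatives except 3 added later were fixed before the data were examined. The named genes followed a rule also fixed then, among protein-coding genes with a mean of at least 1 CPM in the higher group. It took up to 5 genes per direction of largest fold past the threshold, or, with fewer than 3 such genes, filled up to 3 by smallest unadjusted p. It added the member of smallest p from each primary list, or 2 where the list passed camera, and 2 members from the 6 other lists of smallest camera p among those passing. Pde6b, Gfap, Opn1sw, Opn1mw, Aif1 and C1qa were always named. Some genes that the rule selects are not reported here. Genes named outside this rule, Xist among them, are described as chosen after their values were seen.

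Library totals ran from 14640235 to 16989737 counts. The edgeR biological coefficient of variation was 17.1% over all 8 libraries, 8.8% among the PBS libraries alone and 22.3% among the sIVs libraries alone. The tests were checked on simulated counts drawn from the real means and library sizes for 17725 genes. With the spread of all 8 libraries, edgeR recovered 28.4% of genes changed 1.5-fold, 64.2% of those changed 2-fold and 95.5% of those changed 4-fold. Of 17495 unchanged genes edgeR called 6 and DESeq2 42 there. With the spread of the PBS libraries alone it recovered 65.7%, 79.1% and 100%. These simulations gave every library the same spread, unlike the real sIVs libraries. No pair of libraries agreed within sampling noise: the lowest chi-square per gene was 3.67, for PBS library 1 and sIVs library 2, so none was counted as a repeat.

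The alternatives fixed in advance were DESeq2 1.42.0, limma-voom with and without sample quality weights, other scalings, other filters on low counts, limma on log2(FPKM + 0.1) and log2(FPKM + 1), each library left out in turn, blocks by the replicate numbers in the labels, and other thresholds. After the data were seen, 3 more were added: leaving out sIVs libraries 3 and 4, leaving out the 2 libraries without Xist transcripts, and a term for those transcripts. In the other splits of the samples, all 35 splits of the 8 libraries into 2 groups of 4 were refitted. Figures and library values were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The lists of lens, of cornea, of T cells, B cells and neutrophils, and of sex-linked markers had fewer than 5 tested genes in the main test, namely 4, 4, 3 and 2, and were not tested there. Each alternative that leaves out libraries or changes the filter adjusted over its own genes and lists: without sIVs libraries 3 and 4 these were 18261 genes and 45 lists, with lens, cornea and sex-linked markers among them.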

Results

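Gene expression was measured by RNA sequencing of retina from rd10 mice, a model of inherited photoreceptor degeneration. The labels name 2 groups, small intracellular vesicles (4 libraries, sIVs 2 to 5) and phosphate-buffered saline (4 libraries, PBS 1 to 4), and are read here as the treatment given. By its title, the series concerns the delivery of such vesicles and protection of the retina, and the comparison available here asks how the retinal transcriptome differed between vesicle-treated and saline-treated mice. Total counts per library ran from 15039385 to 16989737 in sIVs and from 14640235 to 15948291 in PBS.

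As lists, transcripts of glial reaction, inflammation and interferon response had higher medians in sIVs than in PBS, and rod and cone photoreceptor transcripts lower ones. These lists passed camera with a preset correlation, and none of the 42 lists tested passed with an estimated one (adjusted p = 0.36 for gliosis and cone, 0.457 for inflammatory, 0.556 for rod and interferon genes). The estimated correlation was 0.97 for rod, 0.904 for interferon, 0.488 for gliosis, 0.474 for inflammatory and 0.263 for cone genes, against the preset 0.01. The preset test thus treated genes that varied together as nearly independent. Much of this difference lay in sIVs libraries 3 and 4. The rod list had a median of -1.78 and -1.87 on the log2 scale in these libraries relative to the PBS mean, against 0.07 in sIVs library 2, within the PBS range, and -0.27 in sIVs library 5. Gliosis genes were higher in all 4 sIVs libraries, with list medians of 0.53, 1.80, 1.83 and 1.06 in libraries 2 to 5, while the highest PBS library stood at 0.36. No single gene passed the edgeR quasi-likelihood test after adjustment over 17725 genes.

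**Figure D1:**
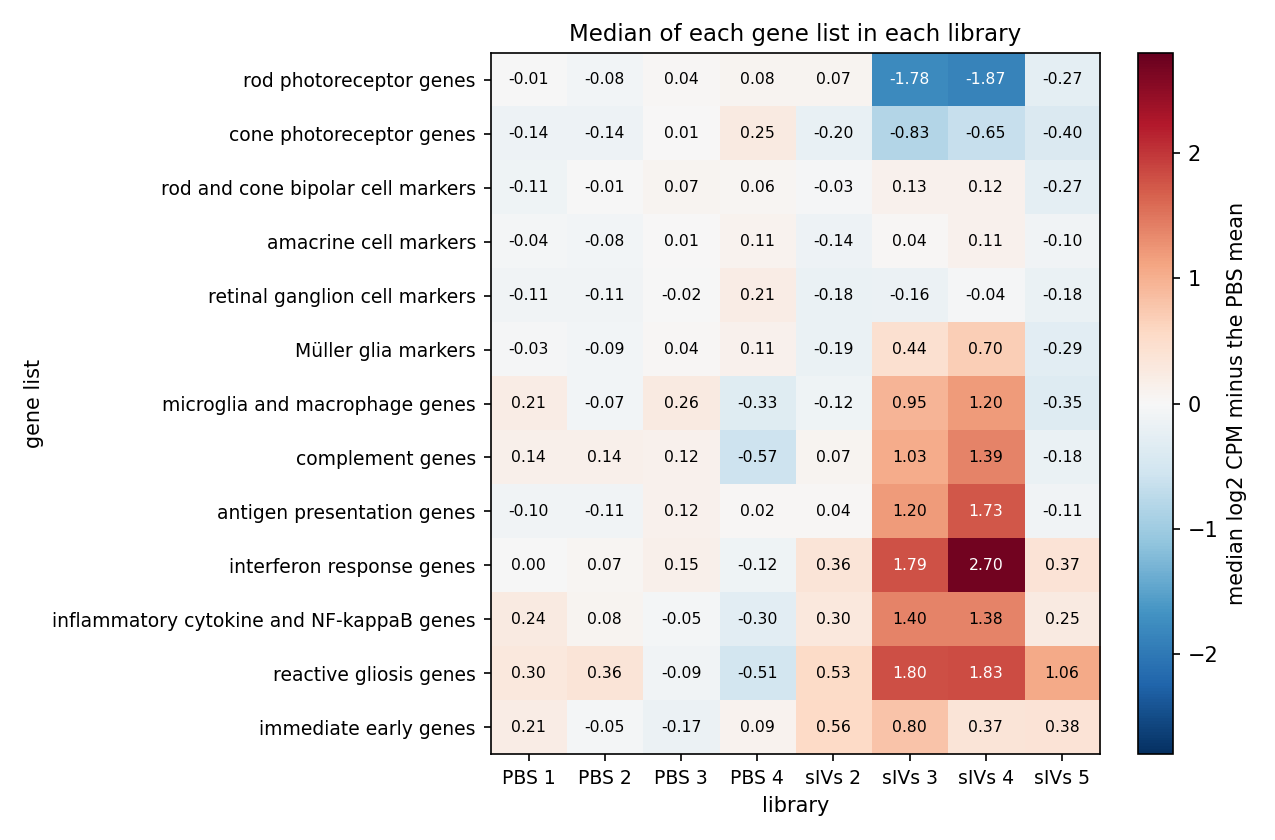
Median log2 CPM of the genes of each list (rows) in each library (columns), relative to the mean of the 4 PBS libraries, as colour and number. Rod genes stand at -1.78 and -1.87 in sIVs libraries 3 and 4, amacrine markers at 0.04 and 0.11, and gliosis genes are above all 4 PBS libraries in all 4 sIVs libraries.

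Photoreceptor lists had negative median fold changes. All 25 rod genes had a negative fold change, with a median log2 fold change of -0.74 (camera with preset correlation, adjusted p = 4.21e-09). With the estimated correlation of 0.97 the rod list did not pass camera (adjusted p = 0.556), and 0 members passed adjusted over the list alone. Pde6b, the gene mutated in rd10 (ENSMUSG00000029491, chromosome 5, 108388391 to 108432397), stood at 1649 ± 75 CPM in PBS and at 1843, 407, 387.3 and 1561 CPM in the sIVs libraries (edgeR adjusted p = 0.533). Susd3 and Rgs9, the rod list members of smallest p, had log2 fold changes of -0.82 and -0.64 (edgeR adjusted p = 0.293 and 0.298). Rgs9 encodes the regulator that speeds the shut-off of phototransduction.

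The cone list had a median log2 fold change of -0.60 (camera adjusted p = 2.98e-07, and adjusted p = 0.36 with an estimated correlation). Of 17 tested members, 9 were lower adjusted over the list alone and 0 adjusted over all genes. Opn1sw, the short-wavelength cone opsin, stood at 426 ± 41.1 CPM in PBS and 157.6 ± 124.2 CPM in sIVs (SD, n = 4 each). It was below every PBS library in 4 of 4 sIVs libraries (log2 fold change -1.44 ± 0.48 SE, edgeR adjusted p = 0.236), and at -2.04 without sIVs library 2 (adjusted p = 0.0196). That pass was not particular to Opn1sw: leaving out sIVs library 2 moved 37 of the 46 named genes past the threshold. With all 8 libraries, Opn1mw, the middle-wavelength opsin, was below every PBS library in 3 of 4 sIVs libraries (edgeR adjusted p = 0.37). Gulo and Cngb3, which encodes a subunit of the cone cyclic nucleotide-gated channel, were lower in 4 of 4 sIVs libraries, with log2 fold changes of -0.73 ± 0.14 and -0.67 ± 0.17 (SE, edgeR adjusted p = 0.153 and 0.173). The outer segment and ciliary list had a median of -0.41 (camera adjusted p = 1.81e-07, and adjusted p = 0.556 with an estimated correlation). Its members of smallest p were Rpgr, a ciliary gene, and Crb1, an apical polarity gene, at -0.43 ± 0.10 and -0.65 ± 0.17 (SE, edgeR adjusted p = 0.167 and 0.177).

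Without sIVs libraries 3 and 4, left out after the data were seen, the rod list did not pass camera (median -0.12, adjusted p = 0.0826). Opn1sw and Opn1mw had log2 fold changes of -0.74 and -0.29 there, and Pde6b turned to 0.04. The outer segment list median turned to 0.01, and the cone list kept a median of -0.30 (camera adjusted p = 2.24e-05, and adjusted p = 0.877 with an estimated correlation).

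**Figure D2:**
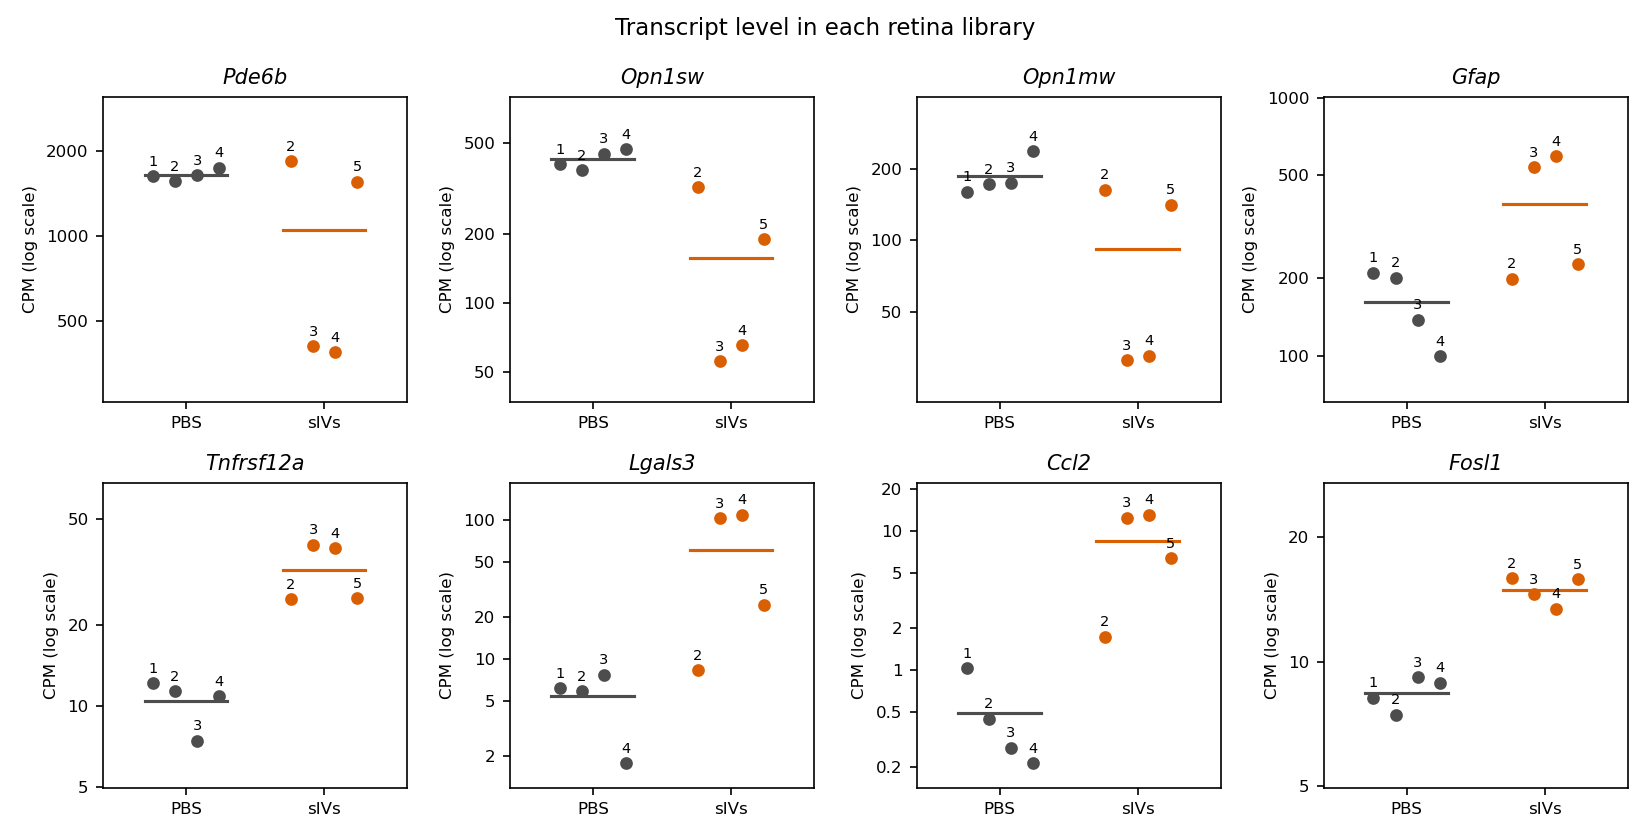
CPM (log axis) of 8 genes in each library. Points are single libraries labelled with their number, and lines are group means (n = 4 each). Pde6b is low in sIVs libraries 3 and 4, at 407 and 387.3 CPM, whereas Tnfrsf12a and Fosl1 are above every PBS library in 4 of 4 sIVs libraries.

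Reactive gliosis genes formed the list with the smallest camera p. Their median log2 fold change was 1.36 (camera adjusted p = 4.08e-16, and adjusted p = 0.36 with an estimated correlation). Of 26 tested members, 24 were higher adjusted over the list alone and 0 adjusted over all genes. Tnfrsf12a, the receptor for the cytokine TWEAK (ENSMUSG00000023905, chromosome 17, 23675445 to 23677468), had the smallest p of all genes. It stood at 10.5 ± 2.09 CPM in PBS and 32.3 ± 8.26 CPM in sIVs (SD, n = 4 each), a log2 fold change of 1.63 ± 0.21 (SE, edgeR adjusted p = 0.0868). Nes, which encodes the intermediate filament nestin, was 1.74-fold higher and above every PBS library in 4 of 4 sIVs libraries (edgeR adjusted p = 0.0868). Gfap, the filament of reactive Müller glia and astrocytes, stood at 162.6 ± 52.5 CPM in PBS and at 199.1, 538.6, 594.1 and 226.4 CPM in the sIVs libraries (edgeR adjusted p = 0.198), with a log2 fold change of 1.26, and of 0.39 without libraries 3 and 4. The gliosis median was 0.80 without sIVs libraries 3 and 4 (camera adjusted p = 4.26e-09, and adjusted p = 0.877 with an estimated correlation).

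Other genes of smallest p pointed the same way in every sIVs library. Choosing genes by p in these same libraries favours such agreement, so it is no separate support. Prss23, a serine protease gene, and Clcf1, an interleukin-6 family cytokine gene, were 2.36-fold and 2.5-fold higher (edgeR adjusted p = 0.0868 for each). Mpdz, a scaffold protein gene, was the lower gene of smallest p, at 166.4 ± 7.23 CPM in PBS and 112.6 ± 11 CPM in sIVs (SD, n = 4 each, log2 fold change -0.56 ± 0.08 SE, edgeR adjusted p = 0.0868). Ankrd31 and Ccdc39 followed, at -1.52 ± 0.29 and -0.41 ± 0.08 (SE, edgeR adjusted p = 0.143 for each). Ankrd31 was low, with means of 1.15 CPM in PBS and 0.396 CPM in sIVs. Immediate early genes, transcribed soon after stimulation, had a median log2 fold change of 0.47 (camera adjusted p = 2.98e-07, and adjusted p = 0.36 with an estimated correlation). Their median was 0.44 without sIVs libraries 3 and 4 (camera adjusted p = 3.09e-06, and adjusted p = 0.877 with an estimated correlation). Of 24 members, 7 were higher adjusted over the list alone. Fosl1, an AP-1 subunit gene, stood at 8.42 ± 0.774 CPM in PBS and 14.9 ± 1.17 CPM in sIVs (SD, n = 4 each, edgeR adjusted p = 0.0868), and Zfp36, which encodes an mRNA-destabilising protein, was 1.91-fold higher (edgeR adjusted p = 0.13).

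Immune lists had positive median fold changes, and the microglial list stood above PBS in sIVs libraries 3 and 4 only. The microglia and macrophage list had a median log2 fold change of 0.56 (camera adjusted p = 0.0228, and adjusted p = 0.755 with an estimated correlation), and 0 of 25 members passed adjusted over the list alone. Its library medians were -0.12, 0.95, 1.20 and -0.35 in sIVs libraries 2 to 5. Aif1, a microglial marker, stood at 2.92 ± 0.376 CPM in PBS and 5.37 ± 3.64 CPM in sIVs (SD, n = 4 each, edgeR adjusted p = 0.398). Siglech, a marker of homeostatic microglia, had a log2 fold change of -1.22 ± 0.34 and Itgam, an integrin of myeloid cells, one of 1.16 ± 0.32 (SE, edgeR adjusted p = 0.185 for each). Genes of disease-associated microglia had a median of 0.62 (camera adjusted p = 4.52e-06, and adjusted p = 0.556 with an estimated correlation), with 6 of 25 members higher adjusted over the list alone. Among these, Lgals3 and Cd63 had folds of 11.4 and 2.15 (edgeR adjusted p = 0.16 and 0.158). By library, Lgals3 stood at 1.55, 19.2, 20.3 and 4.58 times the PBS mean and Cd63 at 1.17, 2.55, 2.84 and 2.05 times in sIVs libraries 2 to 5. The complement list had a median of 0.69 (camera adjusted p = 0.0456, and adjusted p = 0.718 with an estimated correlation), with 2 members higher and 1 lower adjusted over the list alone. The lower one was Cd59a, an inhibitor of the membrane attack complex (log2 fold change -0.44 ± 0.10 SE, edgeR adjusted p = 0.16). C1qa stood at 38.7 ± 10.4 CPM in PBS and 60.7 ± 31.7 CPM in sIVs (SD, n = 4 each, edgeR adjusted p = 0.411). The microglia and macrophage genes and the complement genes did not pass camera without PBS library 4 (medians 0.391 and 0.518), sIVs library 3 (0.405 and 0.536) or sIVs library 4 (0.271 and 0.322). Scaled by library totals they did not pass either (0.651 and 0.782), nor did complement genes on log2(FPKM + 0.1) (0.551).

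Interferon response genes had the highest list median over all libraries, 1.63 (camera adjusted p = 7.03e-14, and adjusted p = 0.556 with an estimated correlation). Without sIVs libraries 3 and 4 it was 0.34, below the gliosis median of 0.80. All 31 had a positive fold change and 29 were higher adjusted over the list alone. Irf9 and Irf1, interferon-regulated transcription factor genes, were 2.34-fold and 2.54-fold higher (edgeR adjusted p = 0.143 and 0.16). The library medians were 0.36, 1.79, 2.70 and 0.37 in sIVs libraries 2 to 5, against a highest PBS value of 0.15. Antigen presentation genes had a median of 0.84 (camera adjusted p = 1.81e-05, and adjusted p = 0.556 with an estimated correlation), with 8 of 20 members higher adjusted over the list alone. These included the peptide transporter gene Tap1 and the immunoproteasome gene Psmb8, at log2 fold changes of 2.00 ± 0.54 and 1.62 ± 0.48 (SE, edgeR adjusted p = 0.18 and 0.196). Inflammatory cytokine and NF-kappaB genes had a median of 1.03 (camera adjusted p = 9.6e-10, and adjusted p = 0.457 with an estimated correlation), with 15 of 24 higher adjusted over the list alone. The chemokine genes Ccl2 and Ccl12 were 16.7-fold and 6.04-fold higher, from PBS means of 0.493 and 0.974 CPM (edgeR adjusted p = 0.13 and 0.136). Ccl2 stood at 3.54, 25.5, 26.7 and 12.96 times the PBS mean in sIVs libraries 2 to 5 and Ccl12 at 3.23, 7.15, 10.3 and 3.80 times. PBS library 1 held 1.03 CPM of Ccl2 and the other 3 at most 0.449, and without it the log2 fold change of Ccl2 moved from 4.06 to 4.71. Psmb8 moved to 1.03 without sIVs library 4.

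Without sIVs libraries 3 and 4 the microglia median turned to -0.28 (camera adjusted p = 0.00333, and adjusted p = 0.877 with an estimated correlation). The medians of disease-associated microglia, complement and antigen presentation genes turned to -0.02, -0.11 and -0.02 and did not pass camera. Aif1 and C1qa turned to log2 fold changes of -0.38 and -0.16. Several others kept their sign at smaller log2 fold changes: Itgam 0.40, Lgals3 1.62, Irf1 0.62, Tap1 0.53, Psmb8 0.38, Ccl2 3.01 and Ccl12 1.79, none past the threshold. Interferon and inflammatory genes had medians of 0.34 and 0.39 there (camera adjusted p = 3.54e-09 and 0.00266, and adjusted p = 0.614 and 0.877 with an estimated correlation).

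Regulated cell death genes had a median log2 fold change of 0.33 (camera adjusted p = 4.37e-06, and adjusted p = 0.36 with an estimated correlation), with 9 of 32 members higher adjusted over the list alone. The median was 0.15 without sIVs libraries 3 and 4 (camera adjusted p = 0.00333, and adjusted p = 0.877 with an estimated correlation). Cdkn1a, a p53 target that arrests the cell cycle, was 2.77-fold higher, and Bid, a pro-apoptotic BCL2 family gene, 1.95-fold (edgeR adjusted p = 0.122 and 0.158). The anti-apoptotic and neurotrophic list did not pass camera (median 0.13, adjusted p = 0.194) but passed the mixed form of fry (adjusted p = 0.0246), with 6 members higher and 3 lower adjusted over the list alone. Its member of smallest p, the survival gene Mcl1, stood at 117.1 ± 11.3 CPM in PBS and 164.6 ± 11.9 CPM in sIVs (SD, n = 4 each, edgeR adjusted p = 0.136). Antioxidant genes had a median of 0.20 (camera adjusted p = 1.49e-05, and adjusted p = 0.457 with an estimated correlation), and 1 of 31 was higher adjusted over the list alone. Hmox1, the haem oxygenase gene, was 4.25-fold higher and Txnrd1, a thioredoxin reductase gene, 1.37-fold (edgeR adjusted p = 0.153 and 0.195). The antioxidant list did not pass without sIVs libraries 3 and 4 (median 0.08, camera adjusted p = 0.116), and Hmox1 moved from a log2 fold change of 2.09 to 1.11. Synaptic transmission genes had a median of -0.13 (camera adjusted p = 4.85e-05, and adjusted p = 0.36 with an estimated correlation), with 0 of 39 passing adjusted over the list alone. Their members of smallest p went opposite ways: the glutamate receptor gene Gria1 at 0.29 ± 0.10 and the postsynaptic scaffold gene Homer1 at -0.29 ± 0.10 (SE, edgeR adjusted p = 0.245 and 0.249).

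Bipolar, amacrine and horizontal cell lists differed in direction between sIVs libraries, and the ganglion cell list overlapped PBS, at -0.18, -0.16, -0.04 and -0.18 in sIVs libraries 2 to 5 against -0.11, -0.11, -0.02 and 0.21 in PBS libraries 1 to 4. Bipolar, amacrine and horizontal cell markers had medians of -0.03, -0.04 and -0.10 (camera adjusted p = 0.515, 0.706 and 0.345). Bipolar markers stood at -0.03, 0.13, 0.12 and -0.27 and horizontal cell markers at -0.11, 0.003, 0.10 and -0.35 in sIVs libraries 2 to 5. Without libraries 3 and 4 both passed camera as lower, with medians of -0.17 and -0.23 (adjusted p = 0.00333 and 0.0087, and adjusted p = 0.877 for each with an estimated correlation). Retinal ganglion cell markers had a median of -0.13 (camera adjusted p = 0.00211, and adjusted p = 0.566 with an estimated correlation), and of -0.22 without sIVs libraries 3 and 4 (camera adjusted p = 0.000375, and adjusted p = 0.877 with an estimated correlation). Cell cycle genes had a median of 0.52 (camera adjusted p = 0.000106, and adjusted p = 0.556 with an estimated correlation) and 0 members passing adjusted over the list alone. Its library medians were 0.05, 0.83, 0.83 and -0.03 in sIVs libraries 2 to 5, and without libraries 3 and 4 its median was 0.03 and it did not pass (camera adjusted p = 0.865). Rrm2 and Kif11, needed for DNA synthesis and spindle assembly, had the smallest p, with log2 fold changes of 2.21 ± 0.67 and 0.69 ± 0.23 (SE, edgeR adjusted p = 0.203 and 0.228), and Rrm2 stood at 0.77 without libraries 3 and 4. Cytosolic ribosomal protein genes had a median of 0.22 (camera adjusted p = 1.43e-12, and adjusted p = 0.556 with an estimated correlation), with 13 of 45 higher adjusted over the list alone. Rpl19 was 1.23-fold higher (edgeR adjusted p = 0.173). Many genes of this family have near-identical pseudogene copies that share reads, so their counts are uncertain. Mitochondrially encoded genes had a median of -0.24 (camera adjusted p = 0.000317, and adjusted p = 0.556 with an estimated correlation), with 4 of 13 lower adjusted over the list alone. mt-Nd4l and mt-Atp6 had log2 fold changes of -0.76 ± 0.18 and -0.33 ± 0.11 (SE, edgeR adjusted p = 0.167 and 0.217), and both overlap a neighbouring gene on the mitochondrial genome.

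**Figure D3:**
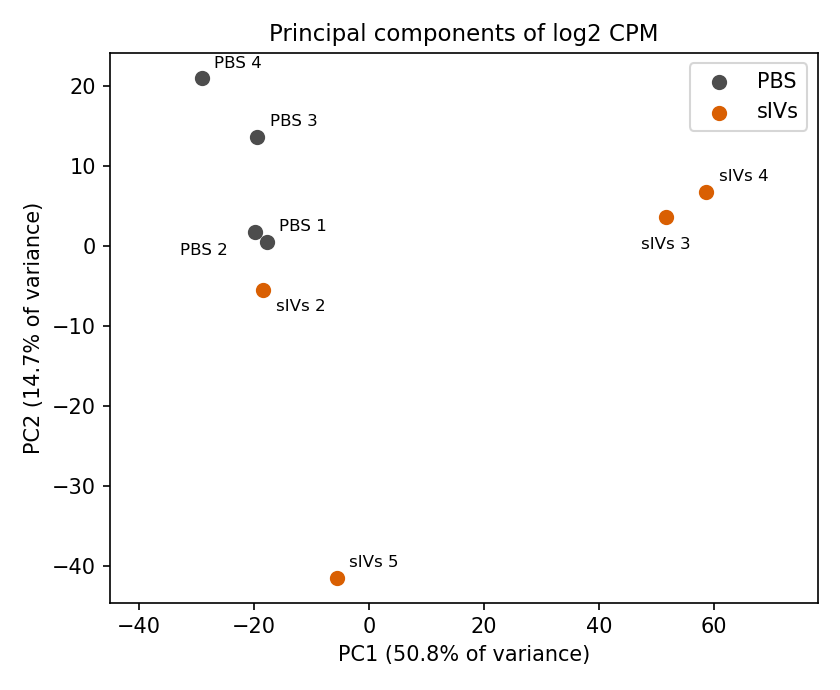
First and second principal components of log2 CPM for the 8 libraries, with the share of variance of each on the axis. sIVs libraries 3 and 4 lie at 51.67 and 58.67 on the first component, and the other 6 libraries lie between -29.08 and -5.65.

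With edgeR, 0 genes were higher and 0 lower at the adjusted threshold, and the smallest adjusted p was 0.0868. At an unadjusted p under 0.05 there were 2702 genes, 1704 higher and 998 lower, against 886 expected by chance. The higher share at this unadjusted threshold was 63.1%, against 82.3% with library totals in place of TMM. It was 52.8% with limma-voom and 49% without sIVs libraries 3 and 4. In 784 genes all 4 sIVs libraries lay above all PBS libraries and in 596 below, against 253 expected by chance in each direction (1.43%). Genes vary together, so counts can stray far from the chance figures for 2702 and 784 genes. Over both directions, 1380 genes had no overlap. Other splits of the libraries with sIVs libraries 3 and 4 on one side had a median of 855.5 and a highest count of 1519, above the real one. DESeq2 gave 33747 genes a p before its own filter, and how many that filter kept for the adjustment is not reported here. It called 466 genes higher and 83 lower, and 522 of these 549 were among the genes edgeR tested. On simulated counts with the spread of all 8 libraries DESeq2 called 42 of 17495 unchanged genes and edgeR 6. Calls were 0 and 0 with limma-voom, 2484 and 2489 with limma-voom with sample quality weights, and 0 and 0 with limma on FPKM values. In edgeR without sIVs library 2 there were 870 higher and 461 lower, without a filter on low counts 145 and 7, and without sIVs libraries 3 and 4 there were 2 and 1. At an adjusted threshold of 0.1 the counts were 10 and 1. Of the 42 lists tested, 20 passed camera with the preset correlation, 0 with an estimated correlation (smallest adjusted p = 0.36) and 0 with directional fry (smallest adjusted p = 0.0955). With fry's mixed form 6 passed. The share of counts from mitochondrial genes was 2.67% ± 0.285 in PBS and 2.47% ± 0.0797 in sIVs (SD, n = 4 each, exact two-sided permutation p = 0.2, adjusted over 7 library measures 0.28).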

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

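The tests of tissue, label swap and rod share, those without sIVs libraries 3 and 4 and that of the other glycolysis genes were chosen, with their bounds, after the result was seen, and the bounds for the counts of splits were written down only then; both tests of sequence shared with Gapdh were set beforehand.

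Single libraries stood far from the other 3 of their group in 15 of 154 groups of 4 values examined, where chance gives about 7.7. PBS library 4 was set apart in Ankrd31 (1.57 CPM), Rgs9 (483.4 CPM), Cd59a (47.95 CPM) and Hmox1 (5.05 CPM). It was also set apart in the list medians relative to the PBS mean of complement genes (-0.57), unfolded protein response genes (0.15) and cell cycle genes (-0.13). PBS library 3 stood apart in Siglech (5.14 CPM), PBS library 2 in antioxidant genes (-0.066) and PBS library 1 in vesicle biogenesis and endosomal genes (0.04). sIVs library 2 stood apart in Prss23 (12.6 CPM) and Crb1 (370.5 CPM), and sIVs library 4 in retinal ganglion cell markers (-0.04). Xist, expressed from the inactive X chromosome of females and chosen after its values were seen, was at 0.213 CPM in PBS library 4 and 0.597 CPM in sIVs library 5, and between 2504 and 2943 CPM in the other 6.

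The first pattern was the low level of rod transcripts in sIVs libraries 3 and 4, with list medians of -1.78 and -1.87 on the log2 scale. A large dilution by tissue other than retina was argued against by amacrine markers, whose lower mean in the 2 libraries was 0.053 ± 0.089 (SE over genes). A small admixture was not ruled out. In libraries 3 and 4, oligodendrocyte and optic nerve marker means were 1.294 ± 0.322 and -0.043 ± 0.278, and lens marker means 0.769 ± 0.42 and 0.919 ± 0.426. The 4 tested lens markers included Cryab, named after its values were seen, which is also on the gliosis list, so the lens means are not specific to lens. Corneal marker means were 0.049 and -0.402 and pigment epithelium means -0.15 and 0.256. The means of the bipolar, amacrine, horizontal and ganglion cell lists spanned at most 0.24 ± 0.09 in either library. That span could not test a lower share of rod cells: PBS library 4, with a rod mean of 0.038, ranged from -0.073 to 0.221. A lower share therefore stayed open for the rod genes. Microglial genes exceeded amacrine markers by at least 0.85 ± 0.16 (SE over genes) in each of the 2 libraries. This error leaves out the spread between libraries, with microglial means from -0.382 to 0.222 in PBS. In the 2 libraries they were 0.903 and 1.084, with amacrine means of 0.056 and 0.053 inside their PBS range. This argued against a lower share of rod cells as the whole cause of the microglial rise. A swap of labels between the groups cannot be told apart: the PBS rod medians all lay within 0.087 of their mean, but sIVs library 2 lay at 0.066, so a swapped partner need not show. A response to the vesicles, a later stage of degeneration, age, litter, and a sample from outside the 2 groups stayed open, as the labels give nothing that separates them.

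The second pattern was the set of genes higher in all 4 sIVs libraries. The adjusted edgeR count was 0 in the real split and in all 35 splits of the 8 libraries, so splits could not test it, while at an unadjusted p under 0.05 4 of the 35 gave as many as 2702 genes (highest other 2825) and 2 of the 35 gave as many as 1380 genes without overlap (highest other 1519), so chance was not excluded for either count. With DESeq2 1 of the 35 splits, the real one, gave as many as 549 genes (highest other 288). The 20 splits that part sIVs libraries 3 and 4 gave at most 3 genes, so they could hardly reach that count. Among the 15 splits that keep these libraries on one side it was 1 of 15, too few for a share under 0.05. Chance was therefore not excluded for the DESeq2 count either. Without libraries 3 and 4 the gliosis and immediate early medians stayed positive, at 0.80 and 0.44. Gliosis stood at 0.53 and 1.06 in sIVs libraries 2 and 5, against a highest PBS value of 0.36. Immediate early genes stood at 0.57 and 0.38 there, against a highest PBS value of 0.21. Whether libraries 3 and 4 alone made these differences could not be tested, as the 2 lists were picked because they had been seen above PBS in all 4 sIVs libraries. They were not the only such lists. Interferon genes (lowest sIVs median 0.362, highest PBS 0.148) and, barely, inflammatory genes (0.248 against 0.243) also stood above every PBS library. Cone genes stood below every PBS library (highest sIVs median -0.201, lowest PBS -0.145). Without libraries 3 and 4 neither passed camera with an estimated correlation (adjusted p = 0.877 for each). A response shared by the treated retinas stayed open, beside handling or sampling differences that the labels do not record.

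The third pattern was Gapdh, the glycolytic enzyme gene, chosen after its values were seen: it stood at 146.7 CPM in sIVs library 2 and 320.1 CPM in sIVs library 5, and between 24.7 and 32.8 CPM in the other 6. Its near-identical copies are a candidate cause of error, since 22.6% of 75-base windows of its transcripts also lay in transcripts of 118 other genes. Gapdh was also low within PBS: at 30.6 CPM its PBS mean lay below that of 23 of the 25 other glycolysis genes. Reads moving from the near-identical copies to Gapdh were argued against, because the summed CPM of Gapdh and the copies rose by at least 0.96 of the rise of Gapdh itself. A rise of glycolysis as a group was argued against by the other 25 glycolysis genes, whose higher median in the 2 libraries was 0.082 ± 0.062. Reads left out as ambiguous in some libraries, a sequence variant and a real change stayed open, as the tables hold gene totals only.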

How the results depend on the processing

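Leaving out sIVs libraries 3 and 4, leaving out the 2 libraries without Xist transcripts and a term for Xist were chosen after the data were seen; the other alternatives were planned. The count of 0 genes higher and 0 lower by edgeR became 466 and 83 with DESeq2 and its own filter, 145 and 7 without a filter, 10 and 1 at an adjusted p under 0.1, 2 and 1 without sIVs libraries 3 and 4, and 2484 and 2489 with sample quality weights, which gave sIVs libraries 2 and 5 weights of 0.258 and 0.245. With each library left out in turn the counts ran from 0 to 870 higher and 0 to 461 lower, and the calls came only without sIVs library 2. The counts were 0 and 0 in the other alternatives, including at least 1.5-fold, both Xist alternatives and other scalings; the cause of the differences was not tested. With library totals the median log2 fold change of all genes moved from -0.005 to 0.071.

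With an estimated correlation, and with directional fry, 11 primary lists lost their call at medians that do not depend on the test: rod -0.737, cone -0.596, outer segment -0.408, gliosis 1.359, microglia 0.555, disease-associated microglia 0.615, complement 0.689, inflammatory 1.032, cell death 0.330, antioxidant 0.203 and synaptic -0.129. With fry's mixed form, cone, gliosis, cell death and anti-apoptotic genes passed (adjusted p = 0.0494, 0.0246, 0.0494 and 0.0246). With library totals, microglia (0.651) and complement (0.782) lost theirs, and with log2(FPKM + 0.1) complement (0.551) did. With each library left out in turn, the microglia median ran from 0.271 to 0.742 and the complement median from 0.322 to 0.875, and both lost their call without PBS library 4, sIVs library 3 or sIVs library 4. Without sIVs libraries 3 and 4, rod (-0.124) and antioxidant (0.076) lost their call, and outer segment (0.007), microglia (-0.279), disease-associated microglia (-0.018), complement (-0.113) and antigen presentation (-0.024) changed sign; the cause was not tested. There cell cycle (0.028), unfolded protein response (0.019) and vesicle biogenesis (0.05) lost their call too, and bipolar (-0.172), horizontal (-0.229) and Müller glia (-0.209) gained one.

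Same-number correlations of deviations gave no sign of pairing: they were -0.006, 0.055 and -0.06 by title and -0.075, 0.041, 0.098 and 0.07 by description. Different-number correlations ran from -0.129 to 0.098 by title. So few pairs cannot exclude a pairing. A replicate block by either number left 0 genes higher and 0 lower. Of 1102 values of the 46 named genes under alternatives, 972 stayed on their side of the threshold and 130 passed it: 30 genes with DESeq2, 45 with quality weights, 17 without a filter, 37 without sIVs library 2 and 1 without sIVs libraries 3 and 4. Pde6b, Aif1 and C1qa changed sign without sIVs libraries 3 and 4, none of them past the threshold.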

Other observations

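Müller glia markers did not pass camera as a list (median log2 fold change 0.15, adjusted p = 0.293), but members moved apart: 5 were higher and 3 lower adjusted over the list alone. Library medians were -0.19, 0.44, 0.70 and -0.29 in sIVs libraries 2 to 5, and without libraries 3 and 4, left out after the data were seen, the list turned to -0.21 and passed camera (adjusted p = 0.00807, and adjusted p = 0.877 with an estimated correlation). Among the higher were Vim, a filament gene also on the gliosis list, at 1.28, and the transcription factor gene Sox9 at 0.64; Glul, which encodes glutamine synthetase, was lower at -0.96 (edgeR adjusted p = 0.0057, 0.0311 and 0.0057, adjusted over the list alone). These genes were chosen after their values were seen. Astrocyte markers had a median of 0.13 (camera adjusted p = 0.194), with 3 of 10 members higher adjusted over the list alone. Oligodendrocyte, vascular endothelial, pericyte, and fibroblast and matrix lists had medians of 0.44, 0.14, 0.32 and 0.18 (camera adjusted p = 0.515, 0.166, 0.166 and 0.166). All 4 medians turned sign without sIVs libraries 3 and 4, to -0.24, -0.01, -0.08 and -0.07, and none passed. The oligodendrocyte list stood at -0.10, 1.34, -0.21 and -0.67 in sIVs libraries 2 to 5, above 0 in library 3 alone. Retinal pigment epithelium, ciliary body and iris, melanocyte, skeletal muscle and erythroid lists had medians of -0.11, -0.15, -0.09, -0.18 and -0.44 (camera adjusted p = 0.986, 0.249, 0.486, 0.32 and 0.0533). The pigment epithelium list also varied within PBS, from -0.72 in library 2 to 0.89 in library 3.

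Vesicle biogenesis and endosomal genes had a median of 0.11 (camera adjusted p = 0.00277, and adjusted p = 0.457 with an estimated correlation), with 3 of 29 members higher adjusted over the list alone: Flot1, Cd63 and Anxa2, of which Flot1 and Anxa2 were chosen after their values were seen. Unfolded protein response genes had a median of 0.11 (camera adjusted p = 0.0183, and adjusted p = 0.556 with an estimated correlation), with Atf3 and Eif2ak3, also chosen after their values were seen, the 2 members higher adjusted over the list alone. Neither list passed without sIVs libraries 3 and 4: vesicle genes had a median of 0.05 and unfolded protein response genes 0.02 (camera adjusted p = 0.0826 and 0.176). Lists of nuclear-encoded oxidative phosphorylation, glycolysis, heat shock, circadian clock, autophagy and lysosome, cholesterol synthesis and replication-dependent histone genes had medians of -0.05, -0.05, -0.01, 0.01, 0.06, -0.09 and -0.37 and did not pass camera (adjusted p = 0.141, 0.371, 0.894, 0.865, 0.0848, 0.166 and 0.0693). Of these, glycolysis, circadian clock and cholesterol synthesis turned sign without sIVs libraries 3 and 4, to 0.07, -0.03 and 0.05, and did not pass there either. Without sIVs libraries 3 and 4, Gm10241, a gene chosen after its values were seen, was lower (log2 fold change -1.28 ± 0.15 SE, edgeR adjusted p = 0.0172), and Gapdh and Tnfrsf12a were higher at 2.93 ± 0.21 and 1.26 ± 0.16 (SE, edgeR adjusted p = 0.000232 and 0.0336).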
